A study of Mus musculus with 27 samples.

How the data were processed

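RNA was measured by sequencing in 27 samples of mouse CD4+ and CD8+ T cells. Per the labels' protocols, T cells were negatively sorted with magnets from pooled lymph node and spleen, cultured for 48 h with IL-7 at 5 ng/ml or with plate-bound antibodies to CD3 and CD28 at 10 µg/ml, and sorted as live cells. Total RNA was fragmented by ultrasound, an adaptor was ligated to the 3′ ends, and the product was amplified by PCR in 12 to 14 cycles. The labels name neither depletion of ribosomal RNA nor selection of polyadenylated RNA. Per the submitters' processing notes, reads were aligned with STAR 2.6.0a to GRCm38. The counting program, its annotation and its strand setting are not given in the sources used here.

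The values used are counts of reads per gene, deposited by the authors as 1 table for all 27 libraries. The table has 26802 genes, of which 26753 were matched by Ensembl gene ID to the reference annotation and 49 were not. Genes that overlap, lie antisense or have close paralogs or pseudogenes, such as ribosomal protein genes, Gapdh, Npm1, Ldha, histone genes and the Ifi20x family, are uncertain where the counting could split or drop their reads. The 45S ribosomal RNA precursor Rn45s held 81.1% to 88.4% of the counts of each library. It was left out before scaling and testing, a decision made after the data were seen, and the results with it kept are given in the closing section. Non-Rn45s counts were 1522199 to 2515583 per library (median 1870270) and protein-coding counts 410808 to 1518324 (median 682031). A tested protein-coding gene had a median of 32 counts per library, and the common biological coefficient of variation was 0.187.

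Groups followed the labels: genotype, subset and culture, with 3 libraries in each of 9 groups. Library numbers 1, 2 and 3 go with the library codes StP212, StP213 and StP219, except that all 3 Rictor KO libraries carry StP219. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples. Outside the Rictor KO comparisons, libraries correlated more with their own number in the other group than, on average, with its other numbers. The exceptions were number 3 for stimulation in Raptor KO CD8+ cells and number 2 for Raptor KO against WT in resting CD8+ cells. Own-number correlations ranged from -0.02 to 0.367. The main tests leave this shared structure out. Replicate libraries were tested for being copies of each other, and each pair differed beyond counting error, with a chi-square per degree of freedom of 1.34 to 5.01.

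Testing used edgeR 4.0.16 in R 4.3.3: a filter for low counts by group (minimum count 10, minimum total 15), TMM scaling, a negative binomial model with 1 mean per group over all 27 libraries, and robust quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. Of 15 comparisons, 12 were between groups and 3 were interactions: the difference of the stimulation effects of Raptor KO and WT in each subset, and the difference of the Raptor effects between the stimulated subsets. Gene lists, 37 in number, were fixed beforehand. Those with at least 5 tested members, 35, were tested with camera of limma 3.58.1 with a correlation between genes of 0.01, which compares the members with all other genes, and again with the correlation estimated from the data. The self-contained test fry was also run. Its directional p asks whether the members move on balance one way, its mixed p whether they move in either direction, and neither compares them with other genes. The lists of myeloid and of erythroid and stromal genes had 2 tested members each and were not tested. Members were also adjusted over their list alone. Folds against a group with no counts are given as bounds, with a floor of 3 counts over the group (0.333 to 0.707 CPM). Floors and such bounds cover counting error only.

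Genes named in the text follow a rule: Rptor, Rictor, Cd4, Cd8a and Cd8b1 in every comparison, the first 4 symbols of each list, in each comparison the 5 largest and 5 smallest log2 fold changes among genes past the threshold, and for each list called by camera the 2 members past the threshold with the largest change in the direction of most members. The ranked genes needed a mean of at least 10 CPM and, between groups, no overlap of the libraries (10% of genes would show none by chance with 3 against 3). Predicted genes, pseudogenes and segments of immunoglobulin or T cell receptor genes were left out of the ranking. Outside the rule are Rn45s, Xist, Ddx3y and Malat1, the markers of myeloid cells, and Evl, named from an overlap. A result that would name an item withheld for evaluation is not reported here. Groupings, comparisons, tests, lists, the naming rule and most alternatives were chosen before the data were examined. Those alternatives were median-ratio size factors, no filter or a stricter one (over 5 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, a minimum fold change of 1.5, a block for the library code, libraries left out in turn, code StP219 alone, overlaps at an adjusted p of 0.01 and the estimated correlation. Added after the data were seen were Rn45s kept, scaling to totals with Rn45s and no TMM, protein-coding genes alone, and leaving out the Raptor KO libraries numbered 1 or the resting Raptor KO libraries numbered 3.

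The procedure was tested on simulated data with 10254 genes and the dispersion of these libraries. In it 218 genes were changed, while the real comparison of Raptor KO and WT stimulated CD8+ cells called 1230. Apart from the ATF4 list, the changed genes were drawn from genes above a minimum level. The recovered shares hold for that setting. For Raptor KO against WT in stimulated CD8+ cells, 118 genes were called, 10 of them unchanged by construction (8.48%), and 2.99% of genes changed 1.5-fold, 55.2% of those changed 2-fold and 87.9% of those changed 4-fold were recovered. For the CD8+ interaction 66 were called, 5 of them unchanged (7.58%), with 2.99%, 17.9% and 69.7% recovered. With nothing changed, 1 gene was called and 420 had an unadjusted p under 0.05. Camera found the changed ATF4 list with adjusted p = 5.49e-33, or 6.66e-08 with an estimated correlation, and called 2 other lists. It called 0 lists where nothing was changed. The simulation drew each gene independently, so it does not test camera on correlated genes. In the data the estimated correlation on stimulation of WT CD4+ cells was 0.467 for ribosomal proteins and 0.14 for the ATF4 list. The limits at which the simulation would have stopped the procedure were loosened after its first run. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.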

Results

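RNA was sequenced from mouse T cells of the C57BL/6 strain to ask how loss of Raptor or Rictor alters gene expression before and after stimulation. Raptor, encoded by Rptor, is the defining subunit of the kinase complex mTORC1, and Rictor is its counterpart in mTORC2. CD4+ and CD8+ T cells came from lymph node and spleen of wild-type (WT) mice, of mice in which a CD4-driven Cre recombinase deletes floxed Rptor (Raptor KO), and of mice in which it deletes floxed Rictor (Rictor KO). For 48 h the cells were kept with 5 ng/ml of the survival cytokine IL-7 (called resting here) or on plates coated with 10 µg/ml antibodies to CD3 and CD28 (stimulated), and live cells were then sorted.

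The 27 libraries formed 9 groups of 3. WT and Raptor KO cells of both subsets were present resting and stimulated, and Rictor KO cells were present as stimulated CD8+ cells. Library totals ran from 8640699 to 16817347 counts, with a median of 11985929. The 45S ribosomal RNA precursor, Rn45s, took 81.1% to 88.4% of each total, which left 1522199 to 2515583 counts per library for all other genes and 410808 to 1518324 for protein-coding genes. After the low-count filter 10493 genes were tested, of which 9451 were protein coding. Levels are given as CPM, counts scaled to a common effective library size (the total over tested genes, Rn45s left out, times its TMM factor), as mean ± SD of n = 3 libraries, and changes as log2 fold change ± SE. Unless another test is named, an adjusted p is from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment over all genes tested. On a multidimensional scaling plot of the libraries, the first dimension held 65.5% of the variance and separated all resting from all stimulated libraries, and the second held 5.70%.

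**Figure D1:**
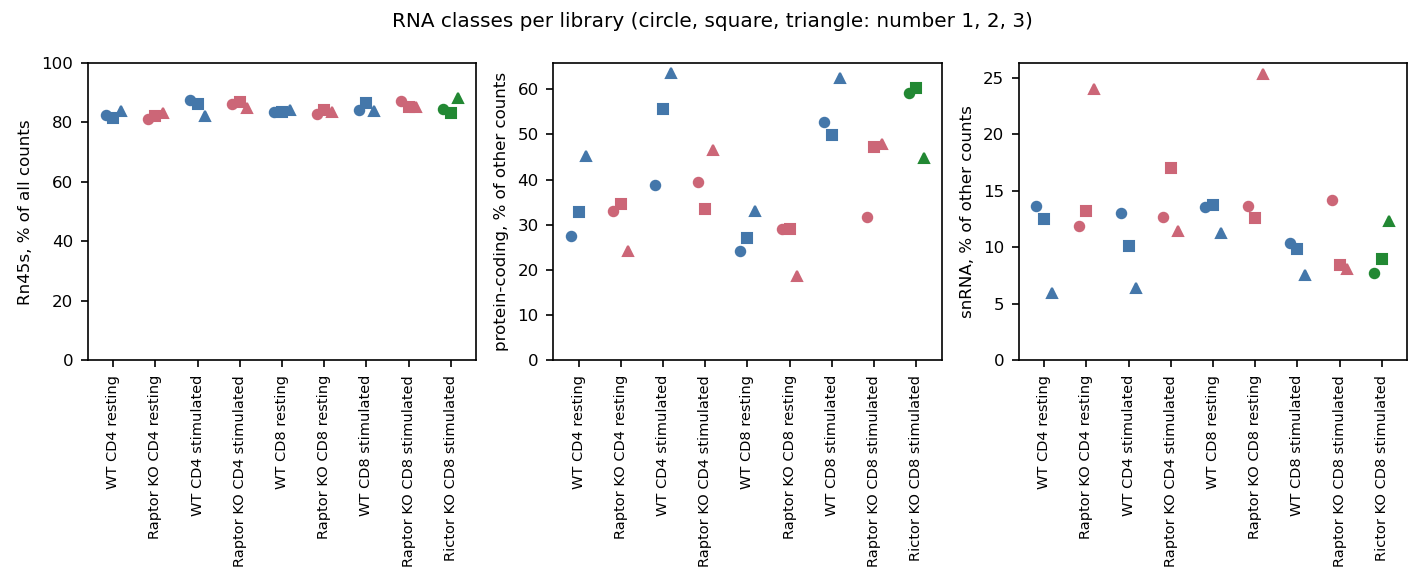
Composition of each of the 27 libraries: the share of all counts on Rn45s in percent, and the shares of the remaining counts on protein-coding genes and on small nuclear RNA (snRNA) in percent, by group, each point being a library and its shape the library number 1, 2 or 3. Rn45s lies between 81.1% and 88.4% throughout, protein-coding genes between 18.7% and 63.6%, and snRNA is highest in the resting Raptor KO libraries numbered 3, at 24.1% in CD4+ and 25.4% in CD8+ cells.

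The targeted genes were examined first as a check of the labels. Rptor (ENSMUSG00000025583, GRCm38 chromosome 11, 119602905 to 119899576) measured 34.5 ± 4.13 CPM in resting and 26.3 ± 3.63 in stimulated WT CD4+ cells, against 27.3 ± 3.65 and 22.1 ± 4.41 in Raptor KO CD4+ cells. In CD8+ cells it measured 45.3 ± 7.49 resting and 23.5 ± 5.27 stimulated in WT, 38.8 ± 3.65 and 19.8 ± 2.68 in Raptor KO, and 27.3 ± 4.31 in stimulated Rictor KO. Its log2 fold change between Raptor KO and WT was -0.25 ± 0.20 in stimulated CD4+, -0.23 ± 0.20 in stimulated CD8+, -0.34 ± 0.20 in resting CD4+ and -0.21 ± 0.19 in resting CD8+ cells, with adjusted p = 0.427, 0.510, 0.741 and 0.802. Rictor (ENSMUSG00000050310, chromosome 15, 6708379 to 6800401) measured 39.1 ± 1.61 CPM in stimulated Rictor KO and 45 ± 7.19 in stimulated WT CD8+ cells, a log2 difference of -0.20 ± 0.16 with adjusted p = 0.961. None of these differences passed the threshold. Counts of a whole gene are a weak check of a floxed allele, because the deleted exons are only part of the gene and the rest can still be transcribed, so the genotypes rest on the labels. The lineage genes separated the subsets: in resting WT cells Cd8a measured 334 ± 61.1 CPM in CD8+ and 3.10 ± 1.34 in CD4+ cells, Cd8b1 317 ± 16.5 and 3.68 ± 1.15, and Cd4 1.5 ± 0.929 and 301 ± 61.7.

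To measure the response to antigen receptor and costimulatory signals in WT cells, stimulated and resting libraries were compared within each subset. Resting cells had IL-7 and no antibody, and stimulated cells had antibody and no IL-7. Each stimulation effect, also in Raptor KO cells and in the differences of stimulation effects, therefore includes the absence of IL-7. In CD4+ cells 3397 genes rose and 3414 fell among 10493 tested, and in CD8+ cells 3363 rose and 3229 fell. Of 28 T cell activation genes, 27 rose in CD4+ and 27 in CD8+ cells, and 27 and 28 adjusted over the list alone. Il2ra, the high-affinity IL-2 receptor chain, rose from 11.7 ± 6.19 to 651 ± 218 CPM in CD4+ cells (log2 fold change 5.76 ± 0.36) and from 2.82 ± 0.612 to 507 ± 58.8 in CD8+ cells (7.46 ± 0.43). Irf4, a transcription factor induced by receptor signalling, changed by 8.19 in CD8+ cells, and in CD4+ cells it stood at 547 ± 89.1 CPM against 0.745 ± 0.772. Naive and quiescence genes fell in 24 of 28 cases in CD4+ and 26 in CD8+ cells (25 and 26 adjusted over the list alone). Among them were Klf2, a transcription factor of quiescent T cells, with -6.76 ± 0.37 and -6.99 ± 0.36, and Il7r, the IL-7 receptor chain, with -4.97 ± 0.43 and -4.24 ± 0.40.

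Cell division genes rose with stimulation. All 28 genes of the G2 and M phases rose in both subsets, with a median log2 fold change of 6.38 in CD4+ and 6.33 in CD8+ cells, or 6.09 and 5.87 when members absent from resting cells are set at their detection bound. DNA replication genes rose in 33 and 34 of 34 cases. Metabolic lists moved the same way: glycolysis rose in 17 and 18 of 22 genes, cholesterol synthesis in 22 and 22 of 24, serine and one-carbon metabolism in 13 and 14 of 14, nutrient transporters in 17 and 17 of 18, and cytosolic tRNA synthetases in all 20. Adjusted over each list alone, these counts were the same in both subsets except cholesterol synthesis in CD8+ cells, with 23. Ldha, which makes lactate from pyruvate, rose from 92.1 ± 6.23 to 962 ± 73 CPM in CD4+ cells (3.38 ± 0.15) and from 79.1 ± 8.94 to 1048 ± 30.9 in CD8+ cells (3.73 ± 0.15). Psat1, an enzyme of serine synthesis, rose by 5.89 and 5.56, and the lipid desaturase Scd2 by 6.44 and 6.46. Genes of the ATF4 response to amino acid shortage rose in 15 and 16 of 18 cases (15 and 16 adjusted over the list alone), with medians of 3.01 and 3.37, or 2.66 and 3.30 with absent members at their bound. Proteasome genes rose in all 31 cases and ribosome biogenesis genes in 54 and 53 of 56 in CD4+ and CD8+ cells.

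Effector genes reached high levels. Effector cytokine genes rose in 13 of 16 cases in CD4+ and 11 in CD8+ cells, the same numbers as adjusted over the list alone. Ifng, encoding interferon gamma, had 0 counts in resting CD8+ cells and 129.7 ± 54.9 CPM after stimulation, at least 185-fold higher. Lif, a cytokine of the IL-6 family, was at least 184-fold higher in stimulated CD4+ cells (112 ± 34.9 CPM). Gzmb, the cytotoxic protease granzyme B, reached 1358 ± 246 CPM in CD8+ and 202 ± 7.84 in CD4+ cells from 0.473 ± 0.819 and 0.171 ± 0.297. The chemokine receptor gene Ccr9 was at least 164-fold lower in stimulated CD8+ cells. The competitive set test camera called 21 lists in CD4+ and 24 in CD8+ cells of 35 tested, and 18 in each subset held with an estimated correlation between genes. Lost were oxidative phosphorylation (rose in 56 and 53 of 73 cases, adjusted p = 0.126 and 0.115 with an estimated correlation), mitochondrial ribosome (54 and 48 of 77, 0.0612 and 0.0648), ribosomal proteins in CD4+ cells (51 of 78, 0.571), and in CD8+ cells cytotoxic genes (0.0589), the hypoxia response (0.289), p53 targets (0.0887) and CD8 lineage genes (0.108). When libraries were instead scaled to totals that include Rn45s, the median of all genes moved by 0.28 in CD4+ and 0.77 in CD8+ cells, and the calls for stimulation in WT CD4 and stimulation in WT CD8 cells became 3098 up and 1936 down and 4524 up and 1130 down.

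The same comparison within Raptor KO cells asked whether cells without Raptor respond to stimulation. In CD4+ cells 2924 genes rose and 2529 fell, and in CD8+ cells 3099 rose and 2733 fell. All 28 activation genes rose in both subsets (also adjusted over the list alone), and G2 and M phase genes rose in 27 and 28 of 28 cases. DNA replication genes rose in all 34 cases, and quiescence genes fell in 23 and 21 of 28. Il2ra changed by 4.45 ± 0.33 and 7.62 ± 0.43, and Klf2 in CD8+ cells by -6.75 ± 0.37. Ifng was at least 244-fold higher in stimulated than resting CD8+ cells, at 173 ± 60.7 CPM against 0, and the growth factor gene Csf2 reached 63.7 ± 33 CPM. Genes of the ATF4 response rose in 5 and fell in 3 of 18 cases in CD4+ cells and rose in 10 in CD8+ cells. Their medians were 0.76 and 1.37, or 0.46 and 1.12 with absent members at their bound. In CD4+ cells camera, which compares them with other genes, gave adjusted p = 0.284, while fry called them higher (adjusted p = 0.000985). In CD8+ cells the camera call was lost (adjusted p = 0.278 with an estimated correlation). Asns, the asparagine synthetase and an ATF4 target, had 0 counts in both resting groups and reached 2.41 ± 1.31 and 4.11 ± 1.31 CPM in CD4+ and CD8+ cells. tRNA synthetases rose in 18 and 20 of 20 cases and serine and one-carbon genes in 11 and 10 of 14, and both calls held in both subsets. Of 21 and 22 lists called by camera, 10 and 11 held with an estimated correlation. Those lost included glycolysis (16 and 16 of 22 genes rose; adjusted p = 0.0509 and 0.0623 with an estimated correlation) and cholesterol synthesis (15 and 18 of 24; 0.305 and 0.170). A minimum fold change of 1.5 lowered the counts to 3291 for stimulation in Raptor KO CD4 and 3806 for stimulation in Raptor KO CD8 cells. Scaling to totals with Rn45s moved the median by -0.12 and 0.30, and gave 1568 up and 1720 down in CD4+ and 2788 up and 1231 down in CD8+ cells.

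The central comparison set stimulated Raptor KO against stimulated WT cells, to show which genes depend on Raptor during activation. In CD4+ cells 925 genes were higher and 898 lower. Genes of the ATF4 response fell in 13 of 18 cases (14 adjusted over the list alone), with a median log2 fold change of -1.92. Asns (chromosome 6, 7675169 to 7693254) measured 2.41 ± 1.31 CPM in Raptor KO and 54.2 ± 17.8 in WT cells, a change of -4.58 ± 0.35 (adjusted p = 3.41e-10). The pseudokinase gene Trib3 changed by -3.01 ± 0.49 and the stress-induced Sesn2 by -3.22 ± 0.32. Chac1, which degrades glutathione, measured 0.190 ± 0.329 against 17.3 ± 2.03 CPM. tRNA synthetases fell in 18 of 20 cases (19 adjusted over the list alone), among them Aars for alanine with -1.82 ± 0.15 and Nars for asparagine with -1.63 ± 0.16. In serine and one-carbon metabolism 8 of 14 genes fell (9 adjusted over the list alone): Psph, the last enzyme of serine synthesis, changed by -2.51 ± 0.23, and Aldh1l2, a mitochondrial folate enzyme, was at least 6.28-fold lower, with 0 counts in Raptor KO cells. Nutrient transporters fell in 10 of 18 cases (11), including Slc7a5, which imports large neutral amino acids, with -2.0 ± 0.26.

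Lipid genes were lower as well. Cholesterol synthesis genes fell in 19 of 24 cases (21 adjusted over the list alone), such as Msmo1 with -1.75 ± 0.20, Lss with -1.73 ± 0.19 and Hmgcs1 with -1.26 ± 0.15. In fatty acid synthesis 11 of 15 genes fell (12), desaturase genes among them: Scd1 changed by -4.18 ± 0.46, Fads2 by -3.63 ± 0.40 and Scd2 by -2.88 ± 0.31, from 863 ± 90.2 in WT to 117 ± 15.9 CPM. Glycolysis genes fell in 14 of 22 cases (15). Ldha was at 441 ± 47.1 against 962 ± 73 CPM (-1.12 ± 0.14) and Slc16a3, a lactate exporter, changed by -1.80 ± 0.34. p53 targets fell in 9 of 21 cases (13), among them the cell cycle inhibitor Cdkn1a with -2.40 ± 0.38. Ribosome biogenesis genes fell in 37 of 56 cases (41), proteasome genes in 23 of 31 (24), ER stress genes in 14 of 23 (15) and G2 and M phase genes in 11 of 28 (11). Aurka, a mitotic kinase, changed by -1.84 ± 0.28.

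Genes that were higher in stimulated Raptor KO CD4+ cells included Zbtb20, a transcriptional repressor, with 3.23 ± 0.33, Gpr183, a receptor for oxysterols, with 119 ± 23.2 against 23.3 ± 3.23 CPM (2.37 ± 0.18), Ms4a4b with 2.68 ± 0.30 and Klf2 with 2.08 ± 0.50. Il2, the T cell growth factor, was lower at 31.5 ± 25.5 against 150.2 ± 96.9 CPM (adjusted p = 0.0269), a call lost with DESeq2 and without the Raptor KO libraries numbered 1. Summed markers of myeloid cells measured 43.3, 45.5 and 50.1 CPM in the stimulated Raptor KO CD4+ libraries and 20.1, 22.3 and 29.7 in WT, most of it Ctss (34.5 and 13.7 on average). Protein-coding genes held 39.5%, 33.4% and 46.5% of non-Rn45s counts in these Raptor KO and 38.9%, 55.5% and 63.6% in WT libraries. Mitochondrial ribosomal RNA held 13.6%, 12.7% and 14.6% against 13.0%, 9.49% and 9.16%. Camera called 20 lists and 12 held with an estimated correlation: the lists named so far for this comparison, all lower. The 8 lost were ribosomal proteins (17 of 78 higher; adjusted p = 0.587 with an estimated correlation), interferon response (7 of 23 higher; 0.0677), regulatory T cell genes (3 of 11 higher; 0.0896), and, all lower, hypoxia (0.237), pentose phosphate (0.0806), mitochondrial ribosome (0.0643), oxidative phosphorylation (0.334) and nucleotide synthesis (0.131). With totals that include Rn45s the median of all genes moved by -0.50, 64 genes were higher and 614 lower, and the ribosomal protein median turned from 0.29 to -0.23. The count for Raptor KO vs WT stimulated CD4 cells was 242 with a minimum fold change of 1.5, and 1197 without the Raptor KO libraries numbered 1, a setting chosen after the data were seen.

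In CD8+ cells the same contrast gave 661 higher and 569 lower genes. ATF4-response genes fell in 15 of 18 cases (16 adjusted over the list alone), with a median of -2.71. Asns measured 4.11 ± 1.31 CPM in Raptor KO and 139 ± 22.3 in WT cells (-5.07 ± 0.29, adjusted p = 3.48e-13). Slc7a3, a transporter of cationic amino acids on chromosome X (101079210 to 101086020), changed by -5.74 ± 0.39, and Gpt2, a mitochondrial alanine transaminase, by -5.32 ± 0.42. Chac1 and Trib3 changed by -3.67 ± 0.40 and -3.93 ± 0.42. tRNA synthetases fell in 15 of 20 cases (18), including Yars for tyrosine with -1.92 ± 0.15 and Aars with -1.82 ± 0.15. Serine and one-carbon genes fell in 8 of 14 cases (8): Psph changed by -2.41 ± 0.21 and Aldh1l2 was at least 18.9-fold lower. Fatty acid synthesis fell in 10 of 15 cases (11) and cholesterol synthesis in 19 of 24 (21), with Scd2 at -2.48 ± 0.31, Mvd at -2.31 ± 0.35 and Dhcr7 at -2.05 ± 0.22. Glycolysis fell in 15 of 22 cases (18), with Pkm at -1.20 ± 0.14, the glucose transporter gene Slc2a1 at -1.43 ± 0.17 and Ldha at 469.7 ± 41 against 1048 ± 30.9 CPM. Hypoxia-response genes fell in 9 of 16 cases (10), among them Vegfa with -3.17 ± 0.40. Nutrient transporters fell in 7 of 18 cases (7), pentose phosphate genes in 5 of 9 (6) and p53 targets in 8 of 21 (12), with Zmat3 at -2.26 ± 0.23.

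Part of the effector genes were higher in stimulated Raptor KO CD8+ cells. Cytotoxic genes rose in 5 of 12 cases (7 adjusted over the list alone; median 0.67), including Ctsw, a protease of killer cells, at 44 ± 2.48 against 9.13 ± 4.57 CPM (2.36 ± 0.25) and Nkg7 at 0.84 ± 0.23, while Gzmb measured 1332 ± 340.0 against 1358 ± 246 and did not pass. Genes of NK and gamma-delta T cells, other cytotoxic cells, were higher in 1 of 5 cases (median 0.76; camera adjusted p = 0.0895, fry 0.0102). Effector cytokine genes were higher in 5 and lower in 1 of 16 cases (7 and 1). Csf2 measured 63.7 ± 33 against 6.92 ± 3.23 CPM (3.12 ± 0.45), and Ccl3 and Xcl1, both chemokines, changed by 2.45 ± 0.52 and 2.47 ± 0.54. Tnfsf10, the death ligand TRAIL, changed by 3.31 ± 0.29 (adjusted p = 2.18e-11), the transcription factor Ikzf2 by 2.09 ± 0.24, and the inhibitory receptor gene Ctla4 by -1.96 ± 0.28. Protein-coding genes held 31.8%, 47.2% and 47.8% of non-Rn45s counts in Raptor KO and 52.9%, 49.9% and 62.5% in WT CD8+ libraries, and mitochondrial ribosomal RNA 10.8%, 14.1% and 15.7% against 10.1%, 10.0% and 7.20%. Summed myeloid markers measured 51.1, 40.8 and 59.98 CPM in Raptor KO and 32.7, 34.8 and 39.6 in WT libraries. Camera called 24 lists and 12 held with an estimated correlation, namely those described for this subset. Lost calls were, for lower lists, proteasome (14 of 31 fell; adjusted p = 0.0595 with an estimated correlation), ribosome biogenesis (9 of 56; 0.317), ER stress (0.143), G2 and M phase (0.321), mitochondrial ribosome (0.0999), oxidative phosphorylation (0.331) and nucleotide synthesis (0.328). For higher lists they were activation (0.143), ribosomal proteins (0.447), mitochondrially encoded genes (0.308), CD8 lineage (0.0708) and regulatory T cell genes (0.167). With totals that include Rn45s the median moved by -0.52, 54 genes were higher and 404 lower, and the medians of activation, ribosomal protein and regulatory T cell genes turned to -0.11, -0.18 and -0.08, while those of cytotoxic and effector cytokine genes went from 0.67 and 0.59 to 0.11 and 0.21. For Raptor KO vs WT stimulated CD8 cells with Rn45s kept among the genes and TMM scaling, 520 were higher and 762 lower, and a minimum fold change of 1.5 left 237 genes.

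**Figure D2:**
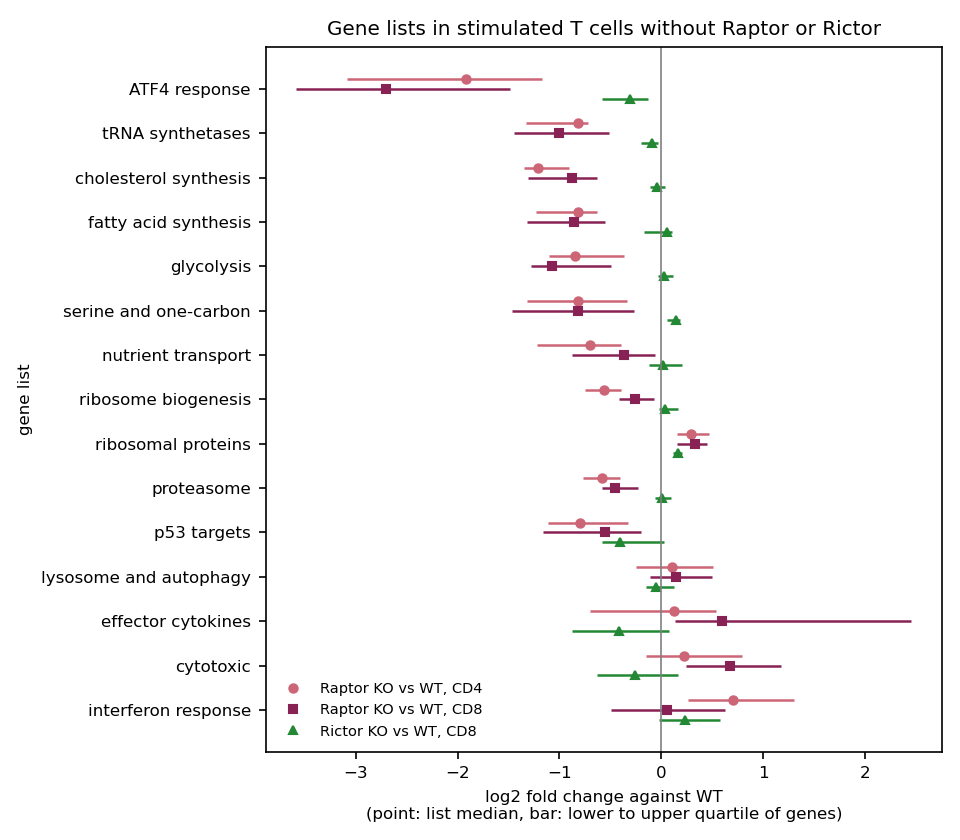
Median log2 fold change (points) and lower to upper quartile of genes (bars) of 15 gene lists in stimulated cells against WT, for Raptor KO CD4+, Raptor KO CD8+ and Rictor KO CD8+ cells. The ATF4-response medians lie at -1.92, -2.71 and -0.30, and the ribosomal protein medians of Raptor KO cells, 0.29 and 0.33, turn to -0.23 and -0.18 when libraries are scaled to totals with Rn45s.

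The Raptor effects in the CD4+ and CD8+ subsets overlapped: 319 genes were higher in both and 324 lower in both, against 58.3 and 48.7 expected of independent lists, and 4 moved in opposite directions. The correlation of log2 fold changes across genes was r = 0.595, and genes are not independent replicates. These contrasts used different WT libraries, though with the same library codes, which the expectation of independent lists leaves out of account. The stimulated Raptor KO libraries numbered 1 had 1474 (CD4+) and 1088 (CD8+) CPM of Xist and 0 of Ddx3y. The subsets may therefore share animals, which the labels do not say and that expectation also leaves out. Whether the effect itself differed was tested as an interaction, which called 18 genes more positive and 17 more negative in CD8+ cells. Tnfsf10 had a difference of 2.54 ± 0.46 (adjusted p = 0.00486), and Trim30a, an interferon-induced gene, had -1.73 ± 0.29 (adjusted p = 0.00197). The transcription factor Rxra had 1.5 ± 0.30 and Zbtb7b, a factor of the CD4 lineage, -2.93 ± 0.58. Camera called 9 lists here and none held with an estimated correlation, where adjusted p = 0.139 for effector cytokines, 0.139 for cytotoxic genes, 0.331 for ribosome biogenesis and 0.25 for the interferon response. At an unadjusted p under 0.05 there were 981 genes. The count of the difference in Raptor effect stimulated CD8 minus CD4 was 57 with DESeq2, 20 with limma-voom, and 3 with a minimum fold change of 1.5.

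**Figure D3:**
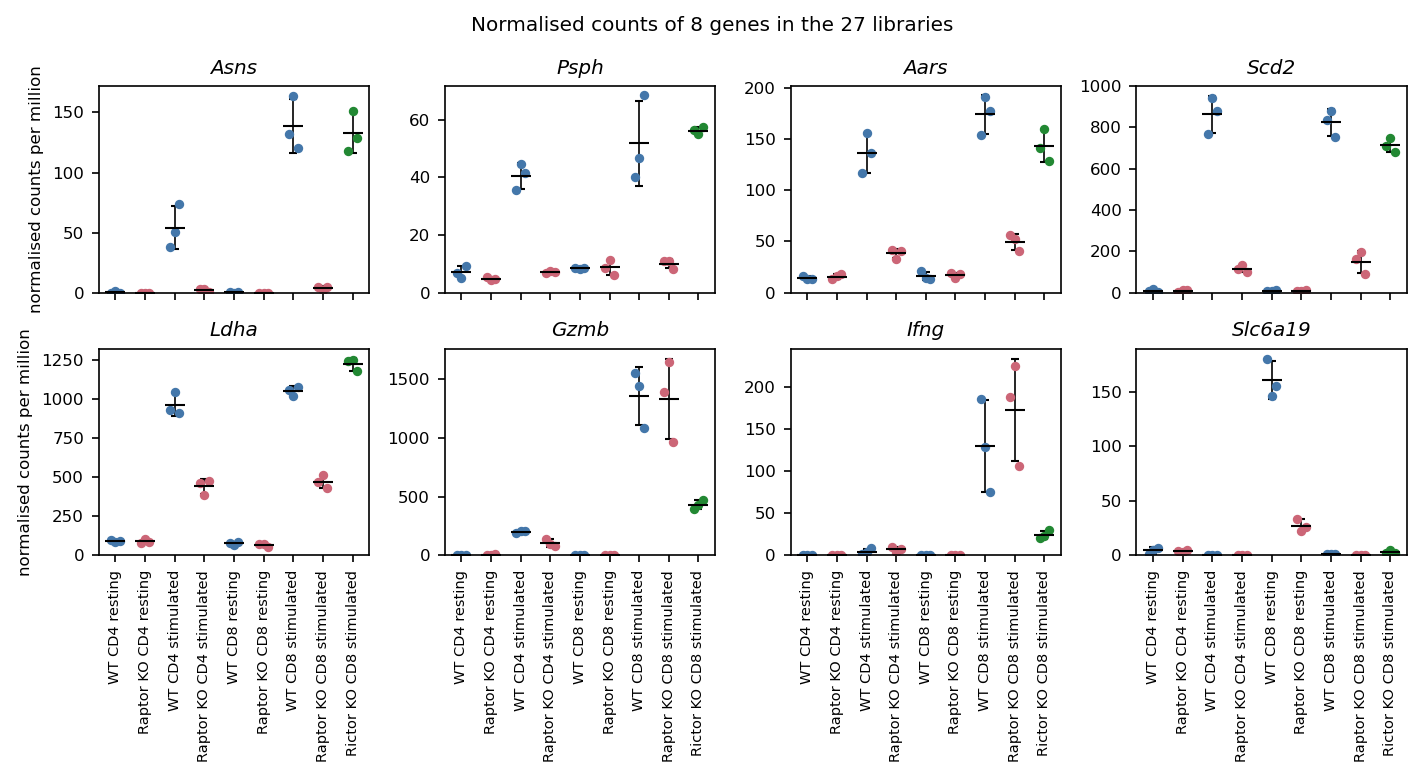
Levels of Asns, Psph, Aars, Scd2, Ldha, Gzmb, Ifng and Slc6a19 in CPM without Rn45s in the 9 groups, each point being a library and each bar the mean of 3 with its SD. Asns averages 54.2 in stimulated WT and 2.41 in stimulated Raptor KO CD4+ cells, and 139 and 4.11 in CD8+ cells, while stimulated Rictor KO cells average 133.

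Whether Raptor changed the response to stimulation itself was tested as the difference between both stimulation effects within a subset. In CD4+ cells 375 genes had a more positive and 236 a more negative effect in Raptor KO cells, and in CD8+ cells 178 and 125. Aars had a difference of -1.97 ± 0.27 in CD4+ and -1.86 ± 0.27 in CD8+ cells, and Yars -2.03 ± 0.28 and -1.95 ± 0.27. tRNA synthetases were more negative in 10 and 11 of 20 cases (13 and 14 adjusted over the list alone), ATF4-response genes in 7 and 8 of 18 (10 and 9), glycolysis in 10 and 9 of 22 (14 and 11) and cholesterol synthesis in 7 and 4 of 24 (15 and 10). Scd2 had -2.85 ± 0.53 and -2.42 ± 0.55. Slc3a2, the partner chain of amino acid transporters, had -1.92 ± 0.22 and the p53 target Ccng1 -1.80 ± 0.26 in CD8+ cells. More positive effects were found for Zbtb20 in CD4+ cells (3.28 ± 0.38) and for Tnfsf10 (3.20 ± 0.41) and the transcription factor Eomes (2.97 ± 0.56) in CD8+ cells. Cytotoxic genes were more positive in 4 of 12 cases in CD8+ cells (4 adjusted over the list alone), with a median of 0.54 that went to 0.03 with totals that include Rn45s. Camera called 21 lists in each subset, and 9 in CD4+ and 10 in CD8+ cells held with an estimated correlation, including all lists named in this paragraph. The counts fell to 80 and 65 with a minimum fold change of 1.5 and to 24 and 39 with totals that include Rn45s, where 5 and 6 were positive. For the difference in stimulation effect Raptor KO minus WT CD4 and the difference in stimulation effect Raptor KO minus WT CD8 they were 299 and 171 without the Raptor KO libraries numbered 1.

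Resting cells were compared to see which genes depend on Raptor without receptor stimulation. In CD8+ cells 53 genes were higher and 65 lower in Raptor KO. The transcription factor genes Bhlhe40 and Myb changed by 4.47 ± 0.69 and 2.48 ± 0.29, and Atp8a2, a phospholipid flippase, by 4.56 ± 0.55. Slc6a19, a transporter of neutral amino acids, measured 27.2 ± 5.75 against 161 ± 17.6 CPM (-2.55 ± 0.21, adjusted p = 9.33e-11), and Dapl1 changed by -3.22 ± 0.43. In CD4+ cells 10 genes were higher and 5 lower, with 816 at an unadjusted p under 0.05. Among them were Ccr9, at 48.6 ± 6.34 against 12.3 ± 4.14 CPM, Atp8a2 with 2.63 ± 0.45 and F2rl1, a protease-activated receptor gene, with -2.10 ± 0.34. Lysosome and autophagy genes rose in 3 of 36 cases in CD8+ cells (8 adjusted over the list alone; median 0.33) and in 2 in CD4+ cells (6; median 0.22). They included Atp6v0d1, a subunit of the lysosomal proton pump, with 1.21 ± 0.31 in CD8+ cells, and Flcn, which encodes folliculin, with 0.81 ± 0.18 in CD4+ cells. The list's camera call held in both subsets, with adjusted p = 0.000649 and 0.00525 with an estimated correlation, and it was the only list called in CD8+ cells.

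In resting CD4+ cells 6 further calls were lost: activation, G2 and M phase, DNA replication and CD8 lineage genes had adjusted p = 0.461 with an estimated correlation, cytotoxic genes 0.0594 and ribosomal proteins 0.507. No ATF4-response or tRNA synthetase gene passed the threshold in resting cells by edgeR. The resting Raptor KO libraries numbered 3 had the highest snRNA shares, 24.1% in CD4+ and 25.4% in CD8+ cells, and those numbered 1 had 1111 and 1061 CPM of Xist with 0 of Ddx3y, a female pattern that the stimulated Raptor KO libraries numbered 1 share and the other 23 libraries do not. Without number 1 the lysosome call in CD4+ cells (adjusted p = 0.0776 with an estimated correlation), Flcn and Atp6v0d1 no longer passed, and without number 3 Atp6v0d1 did not pass. Without number 3 the count for Raptor KO vs WT resting CD8 cells was 71, of which 64 were shared with the full comparison. That count also fell when any other single library of the comparison was left out. It was 23 with totals that include Rn45s and 19 with a minimum fold change of 1.5, which left 5 in CD4+ cells. DESeq2 called 26 genes for Raptor KO vs WT resting CD4 cells.

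Stimulated Rictor KO CD8+ cells were compared with WT to ask what loss of mTORC2 changes. Few genes passed: 11 higher and 6 lower, with 633 at an unadjusted p under 0.05. Ifng (chromosome 10, 118441046 to 118445892) was at 24.4 ± 4.75 CPM in Rictor KO and 129.7 ± 54.9 in WT cells (-2.42 ± 0.37, adjusted p = 0.0204). Lta, the cytokine lymphotoxin alpha, measured 111 ± 31.7 against 226 ± 29 (-1.02 ± 0.20), and Cdkn1a changed by -1.75 ± 0.35, Ndrg1 by -1.36 ± 0.30 and Adam19 by -1.10 ± 0.23. Higher genes included Aff3 with 1.34 ± 0.20 (adjusted p = 0.000721), Trib2 with 1.49 ± 0.24, Plac8 with 1.22 ± 0.24 and Igf1r, the receptor of insulin-like growth factor 1, with 0.96 ± 0.17. Gzmb measured 432 ± 39.8 against 1358 ± 246 CPM and did not pass the threshold by edgeR. Its libraries did not overlap, with 394, 428 and 473 CPM in Rictor KO and 1552, 1441 and 1080 in WT, so no absence of change is shown. Among p53 targets 1 of 21 fell (4 adjusted over the list alone; median -0.40), and this list and that of NK and gamma-delta T cell genes, where Tcrg-C2 rose by 2.16, held with an estimated correlation (adjusted p = 0.00595 and 0.0378). The NK and gamma-delta list has 5 members and its median turned from 1.94 to -0.48 with protein-coding genes alone. No ATF4-response gene passed, and the call of that list was lost (median -0.30; adjusted p = 0.120 with an estimated correlation). Of 14 lists called by camera the other 12 were lost with an estimated correlation: effector cytokines, cytotoxic and helper lineage genes had adjusted p = 0.120 as well, interferon response 0.0682, regulatory T cell genes 0.191, CD8 lineage 0.252, hypoxia 0.311, tRNA synthetases and nucleotide synthesis 0.350, oxidative phosphorylation 0.533 and ribosomal proteins 0.597.

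The count of 17 genes for Rictor KO vs WT stimulated CD8 cells depended on the samples and settings. It ranged from 1 to 27 when a library was left out, with 1 without WT 1, and was 29 with DESeq2, 61 without a low-count filter, 37 when the fit held the compared groups alone, and 5 with totals that include Rn45s. No gene passed in edgeR with a minimum fold change of 1.5. Protein-coding shares of non-Rn45s counts were 52.9%, 49.9% and 62.5% in WT 1, 2 and 3 and 59.2%, 60.4% and 44.8% in Rictor KO 1, 2 and 3. All 3 Rictor KO libraries carry the library code StP219, as does 1 of the WT libraries. Set against that WT library alone, whose spread is taken from the other groups, no gene passed with edgeR.

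Rictor KO and Raptor KO CD8+ cells were compared directly after stimulation, to set mTORC2 against mTORC1. In Rictor KO cells 735 genes were higher and 871 lower. Asns measured 133 ± 17 CPM in Rictor KO and 4.11 ± 1.31 in Raptor KO cells (5.01 ± 0.29), Slc7a3 differed by 6.00 ± 0.38, Gpt2 by 4.87 ± 0.43 and Pck2, a mitochondrial enzyme that makes phosphoenolpyruvate, by 3.47 ± 0.23. ATF4-response genes were higher in 15 of 18 cases (15 adjusted over the list alone), tRNA synthetases in 15 of 20 (16), cholesterol synthesis in 19 of 24 (21) and glycolysis in 15 of 22 (17). Cytotoxic genes were lower in 8 of 12 cases (8) and effector cytokines in 7 of 16 (8). Gzmb was at 432 ± 39.8 against 1332 ± 340.0 CPM (-1.62 ± 0.34), Ifng differed by -2.83 ± 0.37, Csf2 by -4.53 ± 0.51, Ctsw by -3.25 ± 0.27 and Ikzf2 by -2.48 ± 0.24. Camera called 23 lists and 14 held with an estimated correlation, including these 6. With totals that include Rn45s the median of all genes moved by 0.45 and 402 genes were higher and 115 lower. Other scalings shifted the split too: 1040 up and 655 down with Rn45s kept, 962 and 710 with the median-ratio factors, and 942 and 680 with DESeq2. For Rictor KO vs Raptor KO stimulated CD8 cells restricted to code StP219, with 1 Raptor KO library, the count was 716.

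Both knockouts were set against the same stimulated WT CD8+ libraries. Of 10493 genes, 0 were higher in both by edgeR and 2 were lower in both, Cdkn1a and Lta, against 0.693 and 0.325 expected of independent lists. As the contrasts share their controls, 20 simulations of unchanged groups against the same WT libraries were also made, and they gave at most 1 gene changed the same way in both. As neither knockout was changed in them, few genes could pass in either contrast. They therefore set no chance value for the 2 shared genes, where 1230 genes passed in Raptor KO cells. Igf1r and Evl went in opposite directions: Igf1r was at -1.32 in Raptor KO and 0.96 in Rictor KO, and Evl at -0.57 and 0.65. These 4 genes were singled out after their values were seen. The correlation of fold changes was 0.235 and that of the simulations 0.474 (0.435 to 0.499). In the simulations both changes are noise around a shared control, which fixes their correlation, and real changes in Raptor KO cells can lower it. This gap therefore does not show how alike the knockouts are. The covariance was 0.0750 against a simulated 0.0896, a difference of -0.0146. The 3 WT libraries were not split between the contrasts.

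The subsets were also compared within WT cells. In resting cells 167 genes were higher and 182 lower in CD8+ than in CD4+ cells. Besides Cd8a and Cd8b1, Slc6a19 was higher by 5.04 ± 0.27, Nkg7 by 4.10 ± 0.44 and Eomes by 4.07 ± 0.63. Zbtb7b was lower at -5.30 ± 0.44 and Izumo1r, a gene of regulatory T cells, at -3.42 ± 0.54. CD8 lineage genes were higher in all 11 cases, cytotoxic genes in 4 of 12 (5 adjusted over the list alone), CD4 lineage genes lower in 7 of 9 (8) and regulatory T cell genes in 7 of 11 (9). These 4 of 7 camera calls held with an estimated correlation. Activation (0.543), ribosomal proteins (0.717) and CD8 effector and memory genes (0.274) had the adjusted p given with an estimated correlation, and the medians of the other two, 0.32 and 0.01, turned to -0.09 and -0.42 with totals that include Rn45s, which moved the median of CD8 vs CD4 resting WT by -0.41 and left 45 genes higher and 141 lower.

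After stimulation 323 genes were higher and 221 lower in CD8+ cells. Ifng measured 129.7 ± 54.9 CPM in CD8+ and 4.59 ± 3.28 in CD4+ cells (4.58 ± 0.46), Gzmb 1358 ± 246 and 202 ± 7.84 (2.75 ± 0.36), and Prf1, the pore-forming perforin, differed by 3.35 ± 0.38. ATF4-response genes were higher in 6 of 18 cases (8 adjusted over the list alone; median 0.61), such as Cth with 2.12 ± 0.33 and Asns with 1.31 ± 0.20, and tRNA synthetases in 3 of 20 (9). Gata3, a factor of type 2 helper cells, was lower at -2.85 ± 0.34, Il2 at -2.86 ± 0.67 and Ccr8 at -3.94 ± 0.49. Of 6 camera calls, 5 held with an estimated correlation, among them cytotoxic genes (6 of 12 higher; 5.43e-06), ATF4 response (0.00308) and tRNA synthetases (0.0406), and CD8 effector and memory genes had 0.0935. A minimum fold change of 1.5 left 113 genes for CD8 vs CD4 resting WT and 171 for CD8 vs CD4 stimulated WT, and totals with Rn45s left 181 stimulated genes, 121 higher and 60 lower.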

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

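The tests by other groupings of the libraries, the scale and number 1 tests of the ATF4 response, the tests of the lysosome list without libraries and the test of the library code were chosen after the results were seen. The thinning and myeloid tests were chosen before their results were seen.

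A difference between groups singled out the 3 interaction results: 611 genes for which the stimulation effect differed between Raptor KO and WT CD4+ cells, 303 in CD8+ cells, and 35 for which the Raptor effect differed between stimulated CD8+ and CD4+ cells. Other groupings of the libraries were drawn for each. In the CD4+ interaction 4 of 34 groupings, the real one included, gave as many genes as the real one, which gave 511 when the compared groups were fitted alone, against a highest other of 560. In the CD8+ interaction it was 2 of 34, again with the real one (235 against 495), and for the difference of Raptor effects likewise 2 of 34 (18 against 514). By these shares chance is not excluded for the 3 counts. The other groupings that gave as many keep or swap the genotypes of a whole condition or subset, so they carry the difference of genotype there and do not measure chance alone. The drawn groupings that mixed genotypes on both sides gave, by edgeR, at most 2 genes in the CD4+ interaction and 0 in the other two.

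A signal outside the main measurement singled out Rn45s, the ribosomal RNA precursor, whose share of counts was 81.1% or more in every library.

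Genes of the ATF4 response were lower in stimulated Raptor KO CD8+ cells, with a median of -2.71. A shift of scale common to all genes is argued against, since the list median minus that of all genes was -2.74 (quartiles -3.62 and -1.52). The Raptor KO libraries numbered 1, whose Xist counts set them apart, are argued against as well: without them the median was -2.84. Fewer protein-coding counts in Raptor KO libraries were examined by thinning all 6 libraries to 487573 such counts, after which the median was -2.48. Thinning keeps the expected ratio of each gene, so the median could hardly shrink and the test cannot decide this. A different make-up of RNA behind the lower protein-coding shares was not tested. Loss of Raptor itself remains as a hypothesis, which may account for the change, as it was found and tested on these data.

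Lysosome and autophagy genes were higher in resting Raptor KO CD8+ cells, with a median of 0.33. The libraries numbered 3, with high snRNA shares, and those numbered 1 are argued against as the whole source, since the list kept adjusted p = 0.00191 without the former and 0.0304 without the latter. In CD4+ cells these were 0.0399 and 0.0776, so there the call ended without number 1. Myeloid cells, which the negative sort would remove, stay open: summed CPM of their markers differed by 1.87 between Raptor KO (50.4 ± 18.2) and WT (48.6 ± 8.02), against a gain of 208.9 for the lysosome list. The markers among the 5 most abundant of either group measured, in Raptor KO and WT, 24.3 and 33.5 CPM for Ctss, 3.48 and 1.46 for Apoe, 3.27 and 1.33 for Csf1r, 3.14 and 2.07 for Lyz2, 3.08 and 0.813 for S100a9, 2.19 and 2.21 for Cebpb, 1.81 and 2.49 for Mpeg1, and 1.58 and 1.83 for Xcr1.

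For the 17 genes of Rictor KO CD8+ cells, the library code StP219 of all 3 Rictor KO libraries cannot be told apart from the genotype, because 1 WT library carries it. The median ratio of the log2 fold changes against that library to those against all 3 was 0.806 (lowest 0.365, highest 1.19), and 17 of 17 kept their sign. The 17 genes were picked on these same Rictor KO libraries, and that WT library is 1 of the 3. Ratio and signs were therefore partly set in advance. Among 10 splits of the 6 libraries, 2, the real one included, gave as many genes as the real one, which gave 37, and the highest other gave 203. That split put WT 1, WT 2 and Rictor KO 3 together, and it points to a structure of the samples. These 3 libraries had lower shares of protein-coding counts (52.9%, 49.9% and 44.8%) than WT 3, Rictor KO 1 and Rictor KO 2 (62.5%, 59.2% and 60.4%), and whether this accounts for the split was not tested.

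For each of the other comparisons between groups, the 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other gave 5864 and 0 genes for stimulation in WT CD4+, 5977 and 0 in WT CD8+, 4671 and 0 in Raptor KO CD4+, and 4710 and 0 in Raptor KO CD8+ cells. They gave 1500 and 0 for Raptor KO against WT in stimulated CD4+, 1058 and 0 in stimulated CD8+, 114 and 28 in resting CD8+, and 10 and 18 in resting CD4+ cells, where 2 splits, the real one included, gave as many. Rictor KO against Raptor KO gave 1630 and 0, and CD8+ against CD4+ cells 380 and 0 resting and 394 and 0 stimulated. In each comparison of this paragraph but resting CD4+ cells, 1 split, the real one, gave as many.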

How the results depend on the processing

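The alternatives with Rn45s kept, totals with Rn45s, protein-coding genes alone, and libraries numbered 1 or 3 left out were chosen after seeing the data. Where no cause is given, the cause was not tested. Also followed were 7 gene comparisons given in the text as not passing. DESeq2, limma-voom, no low-count filter and the compared groups alone each called 1 of them. Protein-coding genes alone and totals that include Rn45s also called 1 each. Of 1089 named gene calls, those that kept their direction and lost the threshold were 22 with DESeq2, 54 with limma-voom, 33 without a low-count filter, 7 with median-ratio factors, 1 with the stricter filter, 327 with a minimum fold change of 1.5, 63 of 1042 with the compared groups alone, 238 of 1088 with totals that include Rn45s, 13 of 1088 with Rn45s kept, 6 of 1086 with protein-coding genes alone, 98 of 718 without Raptor KO number 1, 38 of 416 without resting number 3, 40 of 110 with code StP219 alone, and 722 of 7218 when a library was left out. A tested protein-coding gene had a median of 32 counts. On simulated data with this depth, spread and n, and 218 of 10254 genes changed, 2.99% of 1.5-fold changes were recovered. This share need not hold where more genes change. How much of the low recovery is due to depth was not tested.

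With DESeq2 the counts that moved were 26 for Raptor KO vs WT resting CD4, 29 for Rictor KO vs WT stimulated CD8 and 57 for the difference in Raptor effect stimulated CD8 minus CD4, and without a low-count filter these were 29, 61 and 75. Limma-voom gave 20 for the last, the compared groups alone 37 and 18 for the last pair, and protein-coding genes alone 53 for the last. With code StP219 alone, which leaves fewer samples, Rictor KO vs Raptor KO stimulated CD8 gave 716 and Rictor KO against WT 0, where the Rictor gene turned to 0.079. At an adjusted p of 0.01 the overlap of Raptor and Rictor effects in stimulated CD8 was 0 and the overlap of Raptor effects in stimulated CD4 and CD8 295. Over all gene lists, 127 of 241 calls held with an estimated correlation. The self-contained test fry called 250, 203 of them shared, and with protein-coding genes alone 241 were called, 235 shared.

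A minimum fold change of 1.5, a stricter test by construction, and totals with Rn45s lowered these counts (fold first, then totals with up and down). For stimulation in WT CD4 totals gave 5034 (3098 and 1936) and for stimulation in WT CD8 5654 (4524 and 1130). The others were 3291 and 3288 (1568 and 1720) for stimulation in Raptor KO CD4, 3806 and 4019 (2788 and 1231) for stimulation in Raptor KO CD8, 242 and 678 (64 and 614) for Raptor KO vs WT stimulated CD4, 237 and 458 (54 and 404) for Raptor KO vs WT stimulated CD8, 5 and 10 (8 and 2) for Raptor KO vs WT resting CD4, 19 and 23 (15 and 8) for Raptor KO vs WT resting CD8, 0 and 5 (1 and 4) for Rictor KO vs WT stimulated CD8, 358 and 517 (402 and 115) for Rictor KO vs Raptor KO stimulated CD8, 113 and 186 (45 and 141) for CD8 vs CD4 resting WT, 171 and 181 (121 and 60) for CD8 vs CD4 stimulated WT, 80 and 24 (5 and 19) for the difference in stimulation effect Raptor KO minus WT CD4, 65 and 39 (6 and 33) for the difference in stimulation effect Raptor KO minus WT CD8, and 3 and 2 (2 and 0) for the difference in Raptor effect stimulated CD8 minus CD4. With Rn45s kept, the interactions gave 607 (291 and 316) and 306 (129 and 177), and with DESeq2 668 (330 and 338) and 345 (168 and 177). Without Raptor KO number 1 the counts were 1197 for stimulated CD4+ cells, 299 and 171 for the interactions and 14 for the difference of Raptor effects, and without resting Raptor KO number 3 71 in CD8+ cells, 64 of them shared.

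Under totals with Rn45s the median of all genes moved by -0.10 (log2) in resting Raptor KO CD4+ cells and by -0.40 and -0.47 for the interactions. Reversed were Akt1s1, Ctsd and Sqstm1 on stimulation of WT CD8+ cells (0.104, 0.102 and 0.268), Ccr7 and Rpl3 in stimulated Raptor KO against WT CD4+ cells (-0.04 and -0.01), and Ccr7 and Rictor in CD8+ cells (-0.037 and -0.029).

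With libraries left out in turn, which lowers n, the ranges were 1138 to 1714 for Raptor KO vs WT stimulated CD4 (1138 without WT 3, 1171 without Raptor KO 1), 753 to 1100 for Raptor KO vs WT stimulated CD8 (753 without Raptor KO 3), 58 to 97 for Raptor KO vs WT resting CD8 (58 without WT 1, 65 without WT 2, 69 without Raptor KO 3, 73 without Raptor KO 2), 10 to 14 resting CD4+, 1 to 27 for Rictor KO vs WT stimulated CD8 (1 without WT 1, 6 without WT 2, 27 without WT 3, 5 without Rictor KO 1 or 2, 3 without Rictor KO 3), 997 to 1443 for Rictor KO vs Raptor KO stimulated CD8 (997 without Rictor KO 2), 375 to 664 for the difference in stimulation effect Raptor KO minus WT CD4 (375 without stimulated WT 3, 394 without stimulated Raptor KO 1), 216 to 288 for the difference in stimulation effect Raptor KO minus WT CD8, and 17 to 45 for the difference in Raptor effect stimulated CD8 minus CD4 (17 and 18 without Raptor KO 2 in CD8+ and CD4+, 18 and 22 without WT CD8+ 2 and 1, 22 without Raptor KO CD4+ 1). The uncalled Gzmb ranged from -0.211 without Raptor KO 2 to 0.151 without Raptor KO 3 for Raptor KO vs WT stimulated CD8. Counts were 6248 to 6790 for stimulation in WT CD4, 6045 to 6471 for stimulation in WT CD8, 4729 to 5108 for stimulation in Raptor KO CD4, 5286 to 5629 for stimulation in Raptor KO CD8, 246 to 283 for CD8 vs CD4 resting WT and 399 to 487 for CD8 vs CD4 stimulated WT.

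With a block for the library code, Raptor KO vs WT resting CD4 gave 34 genes, Raptor KO vs WT resting CD8 197, the difference in Raptor effect stimulated CD8 minus CD4 75, Rictor KO vs WT stimulated CD8 21 (10 shared), gene lists 241 (228 shared), the overlap of Raptor and Rictor effects in stimulated CD8 2 and the overlap of Raptor effects in stimulated CD4 and CD8 820, and 17 named calls lost the threshold. Most libraries correlated more with their own number than with others, which the main tests leave out.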

Other observations

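Lists that camera did not call were also compared in stimulated Raptor KO and WT cells. In CD4+ cells effector cytokines had 0 genes higher and 2 lower of 16 (0.856 by camera), cytotoxic genes 2 and 0 of 12 (0.409), activation genes 6 and 3 of 28 (0.409), CD8 lineage genes 1 and 0 of 11 (0.784) and NK and gamma-delta genes 0 and 0 of 5 by edgeR (0.600). In CD8+ cells interferon response genes had 1 and 3 of 23 (0.673). Of 38 genes of the mTOR pathway, 5 were higher and 4 lower in CD4+ cells (camera adjusted p = 0.611) and 3 and 4 in CD8+ cells (0.449). Of 13 apoptosis genes of the Bcl2 family, 1 was higher and 1 lower in CD4+ (0.531) and 2 and 1 in CD8+ cells (0.722), of 34 DNA replication genes 0 and 2 (0.875), then 1 and 2 (0.680), and of 28 naive and quiescence genes 10 and 2 (0.121), then 3 and 2 (0.496). Of 36 lysosome and autophagy genes 7 and 3 passed (0.292), then 3 and 3 (0.213). CD8 effector and memory genes had 1 and 1 of 15 (0.688), then 2 and 1 (0.851), helper lineage genes 1 and 2 of 17 (0.677), then 3 and 0 (0.109), and CD4 lineage genes 2 and 1 of 9 (0.0759), then 1 and 2 (0.860). B cell genes had 0 of 5 by edgeR in both subsets (0.409 and 0.912). Mitochondrially encoded genes had 0 of 8 by edgeR in CD4+ cells (0.101).

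Stimulation changed some of the targeted pathway's own genes. Rictor changed by -1.73 ± 0.15 in WT CD4+ cells, from 145 ± 12 to 43.8 ± 2.59 CPM, and by -1.71 ± 0.15 in WT CD8+ cells. Rptor changed by -0.97 ± 0.19 in WT CD8+ and -0.99 ± 0.21 in Raptor KO CD8+ cells. The size of these falls depends on the scaling. With totals that include Rn45s the median of all genes on stimulation moved by 0.28 in WT CD4+, 0.77 in WT CD8+ and 0.30 in Raptor KO CD8+ cells. Rictor was higher in stimulated Raptor KO than WT cells, by 0.60 ± 0.16 in CD4+ cells (a call lost without the Raptor KO libraries numbered 1) and by 0.49 ± 0.16 in CD8+ cells, where it turned to -0.03 when libraries were scaled to totals with Rn45s. The noncoding RNA Malat1, outside the naming rule, measured 2454 to 4233 CPM in resting libraries. It measured 287 to 506 in stimulated WT and 702 to 1459 in stimulated Raptor KO libraries, and no test of it is given.

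In helper lineage genes of stimulated Raptor KO CD4+ cells, the median change on stimulation was -0.16, the mean 1.15, and camera called the list higher (adjusted p = 0.0344, or 0.303 with an estimated correlation), so the median and the mean differ in sign. Xist was 1061 to 1474 CPM with Ddx3y at 0 in the 4 Raptor KO libraries numbered 1, and in the other 23 libraries Xist was at most 5.84 and Ddx3y at least 20.7. Series text and labels differ on the dye that marked dead cells, and no value rests on it.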
